A study of Homo sapiens with 15 samples.

How the data were processed

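Total RNA had been extracted with RNeasy kits from segments of human aorta kept frozen, depleted of ribosomal RNA and sequenced as bulk libraries. The labels place 15 libraries in 4 regions of the vessel: 5 of the aortic root, 5 of the ascending aorta, 3 of the arch and 2 of the descending aorta. They name no donor and no covariate. Libraries are numbered within their region, and the numbers have no order.

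The deposited table holds 58288 genes in each of the 15 libraries. Its values are a normalised signal, in which the authors divided the gene counts of each library by a single size factor. Every value was a whole multiple of a step specific to its library, and dividing by that step gave whole reads for 100% of the values, within a tolerance of 0.001 read. The processing notes of the submitters name HISAT2 2.1.0, StringTie 1.3.3b, DESeq2 1.22.1 and the hg38 genome, without saying which step each performed. The release of the gene annotation is not given in the sources used here, and neither is the strand on which reads were counted. Gene positions and classes were taken from GENCODE release 29 (GRCh38), in which 58025 gene identifiers were found without their version suffix, 55619 of them with the same version.

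The recovered reads ranged from 45516476 to 93464847 per library, with a median of 60460055. A single read corresponded to a value between 0.678 and 1.39. Where every library of a group had 0 reads, a fold was computed against 3 reads per library and is given as a lower bound. Where a group held 1 to 3 reads, the ratio is given with a 95% counting interval. Shares of reads in single libraries carry 95% Wilson intervals. Intervals and floors cover counting error only. The deposited scaling differed from size factors recomputed with DESeq2 by at most 0.02 on the log2 scale, and the medians of the libraries lay within 0.04 of each other on that scale.

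Genes were kept where at least 2 libraries, the size of the smallest group, had a value of 10 or more. This left 23916 genes, of which 15819 are protein-coding. XIST, TSIX and Y-linked genes, 564 in all, were left out of every test and table because the donors are human. Values were transformed as log2(value + 1). A linear model with a mean per region was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, and variances were moderated with a mean-variance trend. Differences were tested two-sided for the 6 pairs of regions and for the mean of arch and descending against the mean of root and ascending. A moderated F test asked which genes differed between any of the 4 regions. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. No label says which segments share a donor, and the main fit took the 15 libraries as independent. Its p-values measure only the spread between these samples and ignore any pairing of segments. Libraries within runs of consecutive sample codes, described below, did deviate together (mean correlation 0.394, against -0.0968 between runs).

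Before the data were examined, 41 gene lists were fixed from textbook knowledge of aortic development, the vessel wall and the cell types a segment might hold. Of their 792 members 791 were in the table, and 40 lists had at least 5 kept genes. Lists were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01, and adjusted over the lists of each comparison. The same test was repeated with the correlation estimated from the data. The main tests, the filter and most alternatives were also set before the data were examined, as was the rule for naming genes. For arch against root, ascending against root, descending against arch and distal against proximal, the rule took up to 10 called genes in each direction with the largest change. For the other comparisons it took up to 3 in each direction. Genes named by this rule had to have an established symbol, a mean of 50 or more in the higher group and no overlap between the libraries of both groups. Where fewer than 5 genes passed, up to 5 with the smallest unadjusted p are given as not having passed. For these the symbol and the mean counted, but overlap between libraries was allowed. Up to 4 members of a described list were named by the smallest unadjusted p. Called lists that ended with an estimated correlation and on leaving out 1 library are described only in part. An item withheld for evaluation is not reported here.

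The alternatives were other pseudocounts (0.25 and 4), no filter, quantile normalization, rescaling to equal medians, robust moderation, library quality weights, a fit of the compared regions alone, a block on the order of sample codes, and leaving out each library in turn. Further alternatives were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads. A covariate for adipocyte markers was added after seeing the data. Also after seeing the data, other splits of the libraries were counted for comparisons of groups of at least 3 libraries, as were splits within runs of sample codes.

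The pipeline was tested on simulated counts with 200 changed genes at log2 changes of 1, 2 and 3. For arch against root, limma found 28.4%, 68.7% and 87.9% of them, and 4 of its 127 calls were unchanged genes. For descending against arch the shares were 8.96%, 59.7% and 77.3%. DESeq2 made 200 calls for arch against root, of which 45 were unchanged genes, and edgeR made 123, of which 2 were unchanged genes. All 10 changed lists were called in each of 4 simulated comparisons, and at most 1 of 30 unchanged lists was called in any of them. Genes were simulated independently of each other. The list result therefore does not test the preset correlation on real lists, whose genes can vary together. Libraries were simulated independently too, so the shares above do not cover libraries that deviate together within runs of sample codes.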

Results

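The data are bulk RNA-seq profiles of frozen segments of human aorta, from the root next to the heart to the descending thoracic vessel. The smooth muscle of these regions has different embryonic origins, with cardiac progenitors of the second heart field contributing to the root, neural crest to the ascending aorta and arch, and paraxial mesoderm to the descending aorta. The series addresses differences between cardiac-derived and neural-crest-derived smooth muscle, and the TGF-beta pathway in them. There were 5 root, 5 ascending, 3 arch and 2 descending libraries. The root libraries held 75478535, 49327718, 60460055, 53051565 and 93464847 reads. The ascending libraries held 57334692, 75718077, 67111566, 75677967 and 53403620 reads. The arch libraries held 66823813, 57005597 and 45516476 reads, and the descending libraries 46594549 and 65926738. Rank correlation between libraries across genes, which are not independent replicates, was 0.946 to 0.986. In ascending 1, RN7SL2, a small cytoplasmic RNA gene, took 4.72% of the reads (95% Wilson interval 4.71% to 4.72%), and protein-coding genes took 83.0% (82.9% to 83.0%). Levels below are mean normalised read counts ± SD, with n as given here for each region.

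Arch against root compared the regions at the neural crest and cardiac ends of the study's question. Several transcription factors of the heart were called lower in the arch than in the root. GATA4, a central regulator of heart development (ENSG00000136574; chromosome 8, 11676959 to 11760002), had 924 ± 472 in the root (n = 5) and no read in any of 3 arch libraries, at least 283-fold lower (adjusted p = 0.00211). NKX2-5, a cardiac homeobox factor, fell from 41.8 ± 17.0 to no read, at least 12.8-fold (adjusted p = 0.00369). In the other direction, HOXA3, an anterior HOX gene of the kind that patterns the body axis, (ENSG00000105997; chromosome 7, 27106184 to 27152581), had 1173 ± 376 in the arch and 77.4 ± 84.7 in the root, 15.2-fold higher (adjusted p = 0.00463).

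Several further regulators were lower in the arch than in the root. TCF21, a factor of epicardium-derived cells (chromosome 6, 133889138 to 133895553), had 11.04 ± 5.41 in the arch and 926 ± 355 in the root, 83.8-fold lower (adjusted p = 0.00196). SALL3 fell 99.0-fold, from 298 ± 47.8 to 3.01 ± 2.83, and LHX9 fell from 50.1 ± 10.5 to no read, at least 15.4-fold. HAND1 and GATA5, both cardiac regulators, fell 28.2-fold and 15.7-fold. HAND1 had 103 ± 65.0 in the root and 3.66 ± 6.33 in the arch. Its log2 change of -5.27 ranged from -6.46 to -4.67 when 1 library was left out. IRX2 fell 12.6-fold, STC2, a secreted glycoprotein, 8.38-fold, and PKP2, a desmosome component, 3.81-fold. C8orf49, which starts just past the end of GATA4, had 60.7 ± 40.6 in the root and no read in the arch. Higher in the arch were HOXA2 (15.5-fold), HOTAIRM1, a noncoding RNA of the HOXA cluster (10.3-fold), MAB21L2 (22.8-fold, with 1677 ± 1353 in the arch), POU3F3 (13.9-fold) and GCNT2, a glycosyltransferase gene (6.34-fold, with 3031 ± 543). The HOXA3 gene model spans HOXA4, HOXA5 and HOXA6, HOTAIRM1 and TCF21 each overlap another gene and MAB21L2 lies within LRBA, so the gene of origin of such reads is uncertain.

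**Figure D1:**
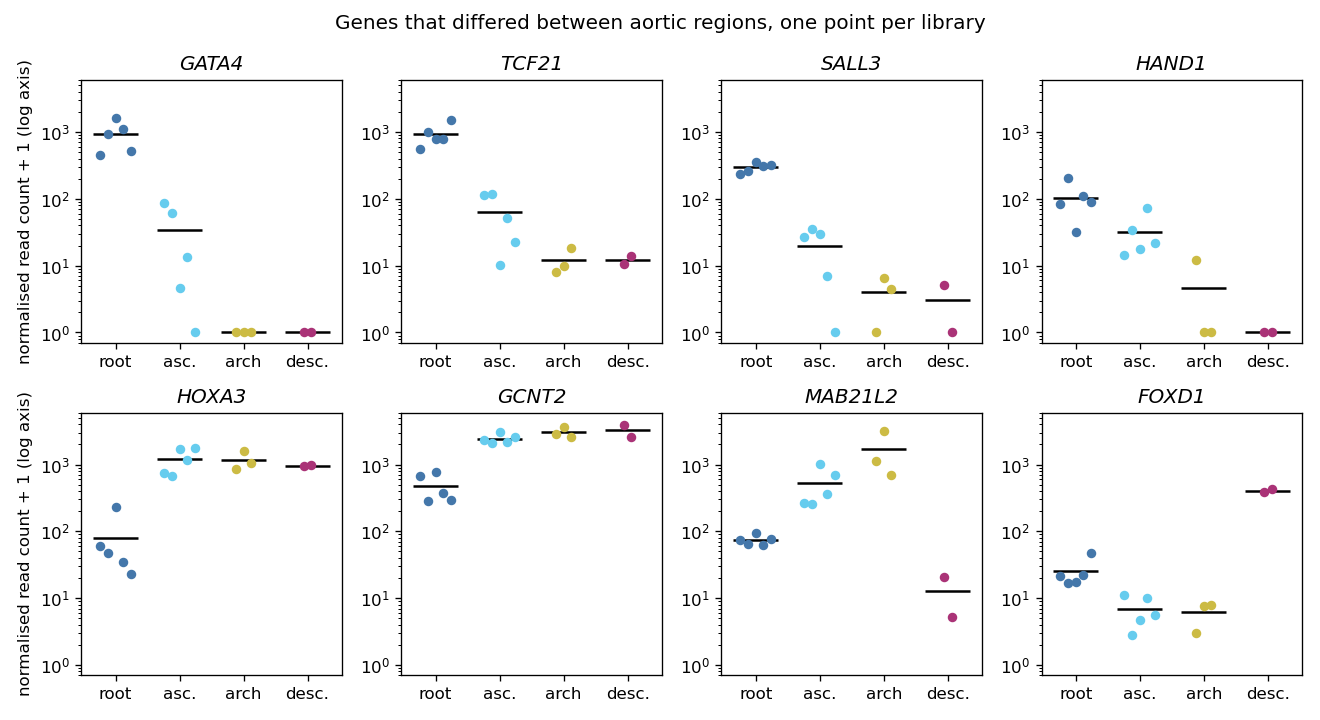
Normalised read counts plus 1 (log axis) of 8 genes in the 4 aortic regions, with a point per library and a line at each region's mean. GATA4, TCF21, SALL3 and HAND1 are highest in the root, HOXA3 and GCNT2 are lowest there, MAB21L2 peaks in the arch and FOXD1 in the descending aorta.

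Among the gene lists, 20 second heart field and cardiac transcription factors fell from root to arch as a group (adjusted p = 1.4e-14, and 0.00117 with an estimated correlation). Of these, 4 were called lower, and 9 were lower and 1 higher when adjusted over the list alone. Adipocyte markers fell as well (adjusted p = 4.6e-28, and 0.0448 with an estimated correlation). All 18 were lower in the arch, none passed over all genes, and 15 passed when adjusted over the list alone. ADIPOQ, the adipocyte hormone adiponectin, had 3817 ± 3019 in the root and 40.9 ± 58.4 in the arch (adjusted p = 0.530), and PLIN4, a lipid droplet protein gene, had 3835 ± 1860 and 778 ± 208 (adjusted p = 0.199). Mesothelial and epicardial markers fell too (adjusted p = 2.1e-08, and 0.0377 with an estimated correlation), with TCF21 called. WT1, a further epicardial factor, had 37.9 ± 33.4 in the root and no read in the arch (adjusted p = 0.157). Cardiomyocyte markers were lower as a group (adjusted p = 0.00675, and 0.462 with an estimated correlation), and in root 3 the heart myosin gene MYH7 had 5910. This list's call ended without root 3 (adjusted p = 0.303) or arch 3 (0.279), and with library quality weights (0.260). Adventitial fibroblast markers were lower in 15 of 19 members (adjusted p = 0.00408, and 0.462 with an estimated correlation).

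Neural crest regulators were higher in the arch as a group with the preset correlation only (adjusted p = 1.97e-04, and 0.234 with an estimated correlation). None of the 22 was called over all genes, while 5 were higher and 2 lower when adjusted over the list alone. DLX1 had 184 ± 125 in the arch and 4.27 ± 3.15 in the root (adjusted p = 0.144), DLX2 had 54.9 ± 38.8 and 0.965 ± 2.16 (adjusted p = 0.129), and TFAP2A had 367 ± 229 and 26.7 ± 27.4 (adjusted p = 0.188). FOXD1, also on this list, went the other way, with 5.20 ± 2.78 and 24.3 ± 12.8 (adjusted p = 0.400). HOX groups 1 to 3 were higher (adjusted p = 0.00508, and 0.368 with an estimated correlation), although HOXB3, at 402 ± 233 in the arch and 1047 ± 331 in the root, was on the opposite side from HOXA3 (adjusted p = 0.566). The call of this list ended without arch 2 (adjusted p = 0.149) or arch 3 (0.0969), and with library quality weights (0.0684). All 29 contractile smooth muscle genes had lower means in the arch, with a median log2 change of -0.39 (adjusted p = 5.4e-08, and 0.462 with an estimated correlation). The call ended without arch 3 (adjusted p = 0.579), and none of the genes was called alone. DES, encoding desmin, had 9384 ± 4919 in the arch and 46448 ± 18815 in the root (adjusted p = 0.456).

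Neither list of the TGF-beta pathway was called between arch and root. Its 35 components had a median log2 difference of 0.04 (adjusted p = 0.792) and its 25 target genes a median of 0.13, against a mean of -0.09 (adjusted p = 0.947). No member of either list was called in the main fit, and 2 target genes were lower when adjusted over the list alone. These were COMP, a matrix protein of cartilage (3717 ± 2150 in the arch, 15741 ± 3467 in the root, adjusted p = 0.0792), and LRRC15 (1.12 ± 1.94 and 29.8 ± 25.3, adjusted p = 0.107). With the block on sample codes limma called both (adjusted p = 0.00685 and 0.0175). Lists not called in the main fit were not examined with the block. Lists of elastic fiber genes (adjusted p = 0.788), heritable aortic disease genes (0.512), modulated smooth muscle genes (0.905), collagens (0.360), Notch (0.325) and Wnt (0.532) components were not called either.

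The call of neutrophil markers followed a single library. These markers were higher in the arch (adjusted p = 0.00111, and 0.462 with an estimated correlation), but CSF3R, a neutrophil receptor gene, had 2350 in arch 2, 293 in arch 1 and 298 in arch 3. Without arch 2 the list's direction reversed (unadjusted p = 0.938). The following lists kept their calls in all 15 fits that left out 1 library. Immediate early genes were higher in 21 of 22 members (adjusted p = 3.4e-09, and 0.462 with an estimated correlation). ATF3 had 5894 ± 3743 in the arch and 2144 ± 2006 in the root, and did not pass. Mitochondrially encoded genes were lower in all 13 members, by a median log2 of -0.25 (adjusted p = 2.0e-06, and 0.376 with an estimated correlation).

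In all, limma called 24 of 23916 genes between arch and root, 8 higher and 16 lower, and 771 had an unadjusted p under 0.05. edgeR called 9 and DESeq2 101. With edgeR, GATA4 (adjusted p = 0.105), NKX2-5 (0.231), C8orf49 (0.154) and HAND1 (0.346) did not pass, and neither did HOXA2, POU3F3, SALL3, GATA5, STC2 and PKP2 (0.0599 to 0.0873). With root and arch alone in the fit, HOXA3 (adjusted p = 0.0588), HOTAIRM1 and GATA5 (0.0695 each), HAND1 (0.0919), HOXA2 (0.116), STC2 (0.134) and POU3F3 (0.237) did not pass. A pseudocount of 0.25 ended the calls of POU3F3 and SALL3, no filter that of POU3F3, and quantile normalization those of STC2 and PKP2. Runs of sample codes that go downstream along the aorta, a hint from the labels and not a stated design, were tried as a block. With this block limma called 107 genes, 41 higher and 66 lower, the 24 among them. They included DLX1, DLX2, TFAP2A, PLIN4, WT1, COMP and LRRC15, which are given above as not passing (adjusted p up to 0.0486 with the block). With the adipocyte marker score as a covariate, added after seeing the data, limma called 0, with 848 at an unadjusted p under 0.05. The count was 13 without root 1, 12 without root 2, 15 without root 4, 13 without root 5, 14 without arch 1 and 13 without arch 3. Of the genes named as passing, HOXA2 lost its call without root 2, root 5 or any arch library (adjusted p up to 0.128), SALL3 without any root library, arch 1 or arch 3 (0.149), PKP2 without any root or arch library (0.149), HAND1 without root 1, 2, 4 or 5, arch 2 or arch 3 (0.127) and GATA5 without arch 2 (0.0796) or arch 3 (0.0702). POU3F3 lost it in 12 (adjusted p up to 0.290) and STC2 in 11 (0.185) of the 15 fits that left out 1 library.

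Ascending aorta against root compared neighbouring segments. Anterior HOXA genes were already higher in the ascending aorta: HOXA3 had 1213 ± 521 (n = 5) against 77.4 ± 84.7 in the root (n = 5), 15.7-fold higher (adjusted p = 0.00202), and HOXA2 was 15.9-fold higher. HOTAIRM1 rose 9.30-fold and GCNT2 rose 5.12-fold to 2444 ± 388. Regulators named above were lower in the ascending aorta, though still read there: GATA4 had 32.8 ± 38.8, 28.2-fold lower (adjusted p = 0.0309), and TCF21 had 63.1 ± 51.4, 14.7-fold lower (adjusted p = 0.00988). LHX9 had 3 reads over the 5 ascending libraries, a ratio of 92.8 (95% counting interval 30.6 to 441).

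NKX2-5 was 38.7-fold lower in the ascending aorta (adjusted p = 0.00202). CDH19, a cadherin of Schwann cells, fell 4.94-fold, from 2056 ± 656 to 416 ± 206. EPHA7, an ephrin receptor gene, fell 9.19-fold, HSPB3, a small heat shock protein gene of muscle, 10.2-fold, SGPP2 21.6-fold and PKP2 3.17-fold. Below the threshold, HOXA4 had 143 ± 61.2 against 12.4 ± 8.98 (adjusted p = 0.0561) and MAB21L2 had 522 ± 334 against 73.5 ± 13.01 (adjusted p = 0.0836). DOCK10 (adjusted p = 0.108), ESM1 (0.184) and SNX25 (0.214) did not pass either.

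The 20 cardiac transcription factors fell as a group (adjusted p = 4.3e-10, and 0.00601 with an estimated correlation), with 2 called and 4 lower when adjusted over the list alone. HOX groups 1 to 3 had 2 called members, and 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.00148, and 0.269 with an estimated correlation). Adipocyte markers were lower in all 18 members, with 0 called by limma and 12 lower adjusted over the list alone (adjusted p = 3.2e-20, and 0.121 with an estimated correlation). FABP4, a fatty acid carrier gene, had 793 ± 636 in the ascending aorta and 3090 ± 2186 in the root (adjusted p = 0.489). Adventitial fibroblast markers were lower in 16 of 19 members (adjusted p = 8.9e-05, and 0.346 with an estimated correlation). LUM, encoding lumican, had 3450 ± 2378 and 9974 ± 3120 (adjusted p = 0.563). Schwann cell and nerve markers were lower in 13 of 15 members (adjusted p = 1.5e-05, and 0.346 with an estimated correlation). Contractile smooth muscle genes were lower in 27 of 29 members (adjusted p = 1.4e-05, and 0.631 with an estimated correlation), a call that ended without ascending 4 (adjusted p = 0.0530).

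Mesothelial and epicardial markers were lower in 9 of 12 members, with TCF21 called (adjusted p = 8.1e-06, and 0.121 with an estimated correlation), and the call held whichever library was left out. Cardiomyocyte markers were lower in 13 of 14 (adjusted p = 0.00497, and 0.464 with an estimated correlation), until root 3 (adjusted p = 0.535), ascending 3 (0.0636) or ascending 4 (0.0567) was left out. Mitochondrially encoded genes were lower in all 13 members (adjusted p = 9.1e-06, and 0.346 with an estimated correlation).

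Between ascending aorta and root limma called 17 genes, 7 higher and 10 lower, with 806 at an unadjusted p under 0.05. edgeR called 12 and DESeq2 80, and limma with the adipocyte covariate called 2. With edgeR, GATA4 (adjusted p = 0.240), NKX2-5 (0.200), SGPP2 (0.159), HSPB3 (0.0576) and CDH19 (0.0520) did not pass. With root and ascending alone in the fit, HOXA2 (adjusted p = 0.0728), HSPB3 (0.0820), PKP2 (0.0928), GATA4 and CDH19 (0.112 each) did not pass. A pseudocount of 0.25 ended the calls of GATA4 and SGPP2, and no filter that of SGPP2. With the runs of sample codes as a block limma called 125 genes, 37 higher and 88 lower, the 17 among them, and also HOXA4, MAB21L2, DOCK10, ESM1, SNX25 and LUM (adjusted p up to 0.0205). Without the block, the count fell to 8 without root 1, without root 2 or without root 5. HOXA2 lost its call without root 2 (adjusted p = 0.0631) or root 5 (0.0502) and EPHA7 without root 1 (0.0512) or root 5 (0.0502), while GATA4, SGPP2, HSPB3, CDH19 and PKP2 lost theirs in 9, 11, 8, 9 and 7 of the 15 fits that left out 1 library, with adjusted p up to 0.107, 0.149, 0.0943, 0.113 and 0.0943.

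Arch against ascending aorta compared the regions to which neural crest contributes. No gene passed, and those given here had the 5 smallest p-values in each direction. DLX1, a homeobox gene of neural crest derivatives, had 184 ± 125 in the arch (n = 3) and 15.5 ± 15.4 in the ascending aorta (n = 5), 11.8-fold higher, and DLX2 had 54.9 ± 38.8 and 4.87 ± 6.75, 11.3-fold higher. GATA5 had 17.1 ± 6.51 in the arch and 76.2 ± 35.8 in the ascending aorta, 4.45-fold lower. TRHDE, a peptidase gene, was 3.30-fold higher in the arch and BRINP3 6.40-fold. KIAA1107 had 314 ± 142 and 56.6 ± 126, with 281 in ascending 5 and at most 1.49 in the other ascending libraries. FAM229A, BRICD5, ZNF517 and HAGHL were 3.49-fold, 1.86-fold, 1.92-fold and 1.82-fold lower. Each of these genes had an adjusted p of 1.

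limma called 0 genes here, with 358 at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 3. With the block it also called 0, with 810 at an unadjusted p under 0.05. Neural crest regulators were higher in 16 of 22 members (adjusted p = 1.77e-04, and 0.496 with an estimated correlation). Immediate early genes were higher in all 22 (adjusted p = 1.7e-06, and 0.834 with an estimated correlation) and neutrophil markers in 12 of 13 (adjusted p = 1.7e-06, and 0.62501 with an estimated correlation). Without arch 2, the library with 2350 for CSF3R, these calls ended (adjusted p = 0.0563, 0.0563 and 0.334). The count was 1 without ascending 5 or without arch 2.

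Other lists moved in this comparison as well. Inflammatory genes were higher in 20 of 22 members (adjusted p = 2.9e-05, and 0.834 with an estimated correlation), until arch 2 was left out (0.0563). Interferon-stimulated genes were higher in 18 of 20 (adjusted p = 0.0329, and 0.834 with an estimated correlation), but not without ascending 1 (0.186), ascending 5 (0.230) or arch 2 (0.408). T and NK cell markers were higher in 16 of 20 (adjusted p = 0.0408, and 0.931 with an estimated correlation), not called without ascending 3 (0.344) or arch 2 (0.428) and reversed without ascending 5 (0.665). Endothelial markers were higher in 15 of 18 (adjusted p = 0.0408, and 0.931 with an estimated correlation), not called without ascending 5 (0.254), arch 2 (0.0563) or arch 3 (0.937) and reversed without ascending 3 (0.787). Adipocyte markers were lower in 16 of 18 (adjusted p = 0.00379, and 0.916 with an estimated correlation) and cardiac transcription factors in 15 of 20 (adjusted p = 0.00834, and 0.496 with an estimated correlation), and both calls ended without ascending 2 (0.597 and 0.118). The endothelial call also ended with quantile normalization, equal medians or quality weights, that of T and NK cells with a pseudocount of 4, equal medians or the block, and that of interferon-stimulated genes with quality weights or the block.

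Descending aorta against arch compared the most distal segments. FOXD1, a forkhead transcription factor (ENSG00000251493; chromosome 5, 73444827 to 73448527), had 402 ± 27.8 in the descending aorta (n = 2) and 5.20 ± 2.78 in the arch (n = 3), 77.4-fold higher (adjusted p = 0.00142). HOXB7, a trunk-level HOX gene (chromosome 17, 48607227 to 48633572), had 217 ± 54.7 and 8.24 ± 1.63, 26.4-fold higher (adjusted p = 0.00424). Both MAB21L paralogs were lower in the descending aorta: MAB21L2 fell from 1677 ± 1353 to 11.9 ± 10.7, 141-fold (adjusted p = 7.3e-04), and MAB21L1 fell from 243 ± 28.1 to 14.1 ± 1.67, 17.2-fold (adjusted p = 7.3e-04). The annotated HOXB7 gene overlaps HOXB8 and HOXB9, and MAB21L1 lies within NBEA, so the gene of origin of these reads is uncertain.

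HOX groups 4 to 6 and 7 to 13 rose, with 1 of their genes called alone. All 10 kept genes of HOX groups 4 to 6 were higher in the descending aorta, by a median log2 of 3.17, and 7 passed adjusted over the list alone (adjusted p = 1.9e-29, and 0.00231 with an estimated correlation). All 7 of groups 7 to 13 were higher, by a median log2 of 2.93, with HOXB7 called and 4 passing adjusted over the list alone (adjusted p = 2.8e-19, and 0.00231 with an estimated correlation). HOXA7 had 148 ± 114 and 2.62 ± 4.53 (adjusted p = 0.871), HOXA6 had 49.7 ± 39.8 and 0.747 ± 1.29 (adjusted p = 0.154), HOXB5 had 99.5 ± 48.3 and 6.56 ± 4.64, and HOXD8 had 417 ± 17.0 and 56.7 ± 22.1 (adjusted p = 0.823). HOXB4 was 5.52-fold higher (adjusted p = 0.641) and HOXB6 7.77-fold higher (adjusted p = 0.436), again without passing. The annotated HOXB3 gene overlaps HOXB4, HOXB5 and HOXB6 on the same strand, so the gene of origin of their reads is uncertain. Groups 1 to 3 were higher in 5 of 7 members (adjusted p = 1.2e-05, and 0.0729 with an estimated correlation). IRX1 (9.54-fold higher, adjusted p = 0.370) and SKAP2 (5.19-fold higher, adjusted p = 0.634) did not pass.

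**Figure D2:**
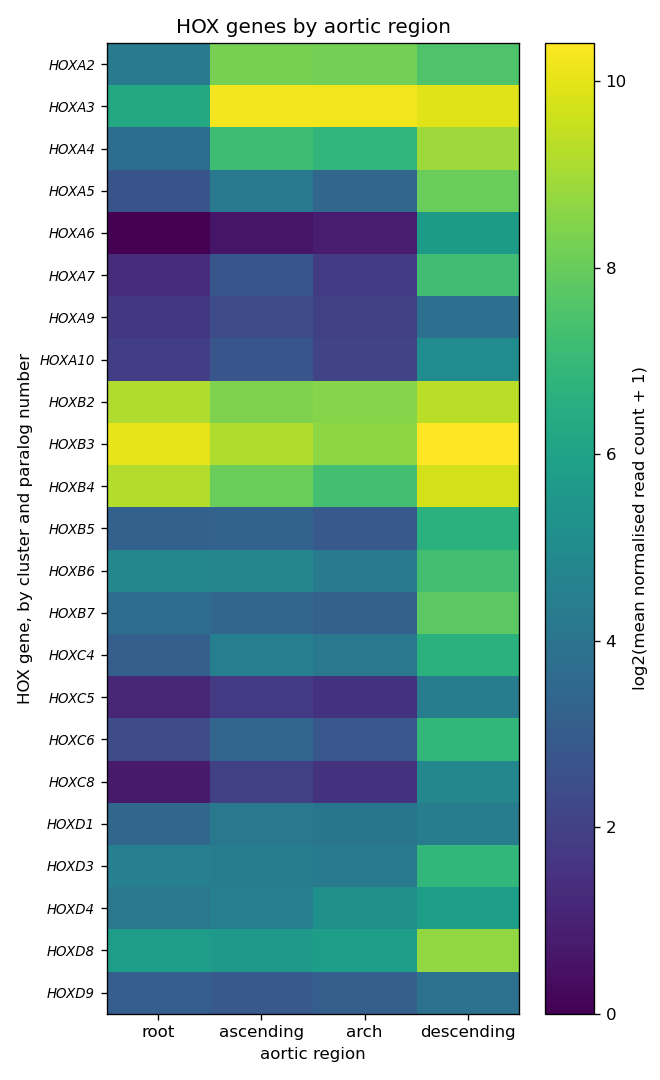
Mean normalised read counts of 23 HOX genes in the 4 regions, as log2(mean + 1) in color, with genes as rows and regions as columns. HOXA3 is lowest in the root (77.4), and HOXB7 is highest in the descending aorta (217).

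Chondrogenic and osteogenic genes fell from arch to descending aorta as a group (adjusted p = 3.9e-05, and 0.00606 with an estimated correlation), with none called and 1 lower adjusted over the list alone. That member was SOX6, a factor of cartilage formation, with 210 ± 12.3 in the descending aorta and 1054 ± 409 in the arch (adjusted p = 0.154). Neural crest regulators were lower in 16 of 22 members (adjusted p = 5.1e-05, and 0.158 with an estimated correlation), although FOXD1, called higher, is among the others. DLX1 and DLX2 had no read in the descending libraries, at least 54.5-fold and 16.2-fold lower than in the arch (adjusted p = 0.272 and 0.688), and TFAP2A was 18.3-fold lower (adjusted p = 0.891). ST8SIA6 (5.42-fold lower, adjusted p = 0.806) and ASTN2 (2.66-fold lower, adjusted p = 0.823) did not pass.

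Further lists were called between descending aorta and arch, none of them with an estimated correlation. Neutrophil markers were lower in all 13 members (adjusted p = 7.6e-09, and 0.158 with an estimated correlation), a call that ended without descending 1 (adjusted p = 0.624). Immediate early genes were lower in 21 of 22 (adjusted p = 4.5e-04, and 0.712 with an estimated correlation), until arch 2 (0.187) or descending 1 (0.914) was left out. Inflammatory genes were lower in 18 of 22 (adjusted p = 0.00130, and 0.712 with an estimated correlation), and without arch 2 were not called (0.0966) and without descending 1 reversed (0.914). Proliferation genes were higher in 19 of 20 (adjusted p = 4.3e-04, and 0.712 with an estimated correlation), not called without arch 1 (0.308) or arch 2 (0.0701) and reversed without descending 2 (0.148). Adipocyte markers were higher in all 18 (adjusted p = 4.7e-04, and 0.712 with an estimated correlation), but not called without descending 2 (0.826). Cardiac transcription factors were lower in 13 of 20 (adjusted p = 0.00681, and 0.158 with an estimated correlation), but not called without descending 1 (0.287).

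Between descending aorta and arch limma called 4 genes in all, 2 higher and 2 lower, with 383 at an unadjusted p under 0.05, edgeR 4 and DESeq2 19, and limma with the block 17. Those 17 included HOXA6, IRX1, SOX6, DLX1, TFAP2A, ST8SIA6 and ASTN2, given above as not passing (adjusted p up to 0.0453 with the block). Without descending 2 the count was 16, without descending 1 HOXB7 (adjusted p = 0.195) and the chondrogenic (0.0531) and neural crest (0.177) lists no longer passed, and with the compared regions alone in the fit limma called 0. A region left with a single library was assumed to vary like the others.

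Descending aorta against root compared the ends of the sampled vessel. Several HOX genes were higher in the descending aorta and several cardiac regulators were lower. HOXA4 had 477 ± 5.99 (n = 2) against 12.4 ± 8.98 in the root (n = 5), 38.4-fold higher (adjusted p = 0.0130), HOXB7 rose 18.2-fold and HOXA6 rose from no read to 49.7 ± 39.8, at least 17.0-fold. The neural regulators POU3F3 and NKX6-1 were each 42.0-fold higher. With 1 library left out, the log2 change ranged from 4.88 to 5.71 for POU3F3 and from 4.36 to 6.32 for NKX6-1. GATA4, HAND1 and NKX2-5 had no read in the descending aorta, at least 273-fold, 30.5-fold and 12.4-fold lower than in the root.

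GATA5 fell 28.8-fold (adjusted p = 0.00728). SALL3 had 3 reads over the descending libraries, a ratio of 143 (95% counting interval 63.3 to 899). COMP fell 12.2-fold, from 15741 ± 3467 to 1294 ± 465 (adjusted p = 0.00651), and SOX6 fell 5.95-fold (adjusted p = 0.00702). HOX genes 1 to 3, 4 to 6 and 7 to 13 rose as groups (adjusted p = 9.1e-11, 6.0e-21 and 1.5e-14, and 0.00598, 0.00523 and 0.00523 with an estimated correlation). All 7, 10 and 7 kept members had higher means, while HOXA3, HOXA4, HOXA6 and HOXB7 alone were called, and some differed little, such as HOXB3 (1047 in the root and 1361 in the descending aorta). Cardiac transcription factors (adjusted p = 3.1e-15, and 9.6e-04 with an estimated correlation) and chondrogenic genes (adjusted p = 6.3e-05, and 0.00578 with an estimated correlation) fell. Contractile smooth muscle genes were lower in 26 of 29 members (adjusted p = 9.1e-05, and 0.616 with an estimated correlation), and without descending 2 the direction of the list reversed (adjusted p = 0.299). Adipocyte markers were lower in 16 of 18 members (adjusted p = 3.0e-10, and 0.261 with an estimated correlation), mesothelial and epicardial markers in 9 of 12 (adjusted p = 9.8e-05, and 0.0838 with an estimated correlation) and mitochondrially encoded genes in all 13 (adjusted p = 2.0e-04, 0.0642 with quantile normalization, and 0.438 with an estimated correlation). Collagens were lower in 19 of 25 (adjusted p = 0.0124, and 0.438 with an estimated correlation), but not called without descending 2 (0.284).

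limma called 33 genes between descending aorta and root, 13 higher and 20 lower, with 997 at an unadjusted p under 0.05. edgeR called 14 and DESeq2 122, and limma with the adipocyte covariate called 3 and with the block 147. With edgeR, GATA4 and HAND1 (adjusted p = 0.222 each), NKX2-5 (0.409), SALL3 (0.158), HOXA6 (0.0822), NKX6-1 (0.0803) and GATA5 (0.0666) did not pass. With these regions alone in the fit, GATA5 (adjusted p = 0.0661), POU3F3 (0.0845), HOXA4 (0.197) and NKX6-1 (0.240) did not pass. A pseudocount of 0.25 ended the calls of HOXA4, NKX6-1, SALL3 and HOXA6, and library quality weights that of NKX6-1. Without the block, the count was 2 without descending 1, where none of the genes named here passed. Without descending 2, HOXA4, NKX6-1, SALL3, HAND1, SOX6, NKX2-5 and GATA5 lost their calls, and NKX6-1 and SALL3 also did so without certain libraries of other regions.

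Descending against ascending aorta compared segments on either side of the arch. FOXD1 was 68.9-fold higher in the descending aorta (n = 2), where it had 402 ± 27.8 against 5.84 ± 3.57 (n = 5, adjusted p = 8.6e-04), and HOXB7 was 22.3-fold higher (adjusted p = 0.00239). MAB21L1 fell 24.2-fold (adjusted p = 1.1e-04) and MAB21L2 43.9-fold (adjusted p = 0.00308). HOX groups 4 to 6 and 7 to 13 rose (adjusted p = 1.25e-16 and 9.0e-13, and 0.0123 for both with an estimated correlation). Cardiac transcription factors fell (adjusted p = 4.3e-05, and 0.0238 with an estimated correlation), as did chondrogenic genes (adjusted p = 5.0e-05, and 0.0123 with an estimated correlation). Collagens were lower in 21 of 25 members (adjusted p = 0.00248, and 0.388 with an estimated correlation), though not called without descending 2 (0.135). Elastic fiber genes were lower in 15 of 18 (adjusted p = 0.0229, and 0.411 with an estimated correlation), though not called without ascending 2 (0.138) or descending 1 (0.157). HOXD8 (8.88-fold higher, adjusted p = 0.251), SKAP2 (5.13-fold, 0.273), HOXB6 (5.81-fold, 0.329), RGS7BP (3.55-fold, 0.360) and RERG (2.19-fold, 0.360) did not pass. Nor did SOX6 (4.46-fold lower, adjusted p = 0.0903), COMP (5.19-fold, 0.329), CLEC18B (4.63-fold, 0.329), SHANK2 (6.03-fold, 0.337) and IRX3 (4.47-fold, 0.360). limma called 7 genes, 4 higher and 3 lower, with 850 at an unadjusted p under 0.05, edgeR 3 and DESeq2 31, and limma with the block 21, with HOXD8, SKAP2 and SOX6 among them (adjusted p up to 0.0451). MAB21L2 did not pass with edgeR (adjusted p = 0.111). With these regions alone in the fit FOXD1 (adjusted p = 0.0698), MAB21L2 (0.192) and HOXB7 (0.237) did not pass. Without descending 1 the count was 4 and HOXB7 did not pass (adjusted p = 0.122), and without descending 2 the count was 27.

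Distal against proximal aorta was tested as the mean of arch and descending against the mean of root and ascending, each region counting alike. Folds and means given here are instead over the 5 distal and the 10 proximal libraries. Several cardiac regulators were lower in the distal aorta, with proximal means that came mostly from the root. Root and ascending means were 924 and 32.8 for GATA4, 41.8 and 1.08 for NKX2-5, and 103 and 31.2 for HAND1. They were 269 and 76.2 for GATA5, and 142.5 and 46.9 for IRX2. GATA4 had no read in the 5 distal libraries and 478 ± 566 in the 10 proximal ones, at least 145-fold lower (adjusted p = 0.00728). HAND1 fell 30.6-fold, GATA5 fell 12.3-fold and IRX2, a homeobox gene, fell 8.15-fold. NKX2-5 was at least 6.48-fold lower (adjusted p = 0.0399), and HOXB7 was 8.47-fold higher (adjusted p = 0.0390), with 91.8 ± 118 in the distal and 10.8 ± 4.34 in the proximal libraries. The HOXB7 difference rested on the 2 descending libraries (217), since its arch mean of 8.24 lay below those of root (11.96) and ascending aorta (9.72).

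Cardiac transcription factors fell as a group (adjusted p = 4.3e-11, and 0.00355 with an estimated correlation), and HOX groups 4 to 6 (adjusted p = 1.2e-10, and 0.0459 with an estimated correlation) and 7 to 13 (adjusted p = 5.7e-09, and 0.0342 with an estimated correlation) rose. These HOX rises rested on the descending libraries, since neither group was called in arch against root (adjusted p = 0.444 and 0.788) or arch against ascending (0.342 and 0.996). Of their 17 members, 4 had an arch mean above both the root and the ascending mean. Chondrogenic genes fell (adjusted p = 5.1e-04, and 0.0312 with an estimated correlation). Among them, SOX6 in the arch (1054) lay between root (1252) and ascending aorta (939), whereas COMP in the arch (3717) lay below both (15741 and 6712). Adipocyte markers were lower in 16 of 18 members (adjusted p = 2.6e-09, and 0.301 with an estimated correlation), and mesothelial and epicardial markers in 8 of 12 (adjusted p = 4.6e-04, and 0.127 with an estimated correlation), with TCF21 called. HOX groups 1 to 3 were higher in 6 of 7 (adjusted p = 8.1e-06, and 0.0558 with an estimated correlation). The calls of these lists held whichever library was left out. Collagens were lower in 21 of 25 members (adjusted p = 0.00425, and 0.335 with an estimated correlation), but not called without arch 3 (0.0862) or descending 2 (0.1198). TBX20, a cardiac T-box gene, had 77.8 ± 125 in the distal and 873 ± 548 in the proximal libraries (adjusted p = 0.0561). SALL3 (60.0-fold lower, adjusted p = 0.0546), GDF6 (2.15-fold, 0.110), SOX6 (1.53-fold, 0.114) and PTN (2.04-fold, 0.136) were lower without passing. HOTAIRM1 (2.11-fold higher, adjusted p = 0.0661), NKX6-1 (12.97-fold, 0.110), FOXD1 (10.9-fold, 0.142), HOXA3 (1.69-fold, 0.179) and HOXA4 (3.33-fold, 0.213) were higher without passing. limma called 18 genes, 5 higher and 13 lower, with 1124 at an unadjusted p under 0.05, edgeR called 8 and DESeq2 70, and limma with the adipocyte covariate called 0, with 1631 at an unadjusted p under 0.05. With the block limma called 55, with HOTAIRM1, NKX6-1, FOXD1, SALL3, TBX20, GDF6, SOX6 and PTN among them (adjusted p up to 0.0442). With edgeR GATA4 (adjusted p = 0.121), HAND1 (0.132) and NKX2-5 (0.589) did not pass. A pseudocount of 0.25 or quantile normalization ended the calls of NKX2-5 and HOXB7, and robust moderation that of NKX2-5. Without the block, the count was 2 without descending 1, where none of the genes named above as passing did so, and 30 without descending 2. NKX2-5 and HOXB7 each lost their calls in 13 of the 15 fits that left out 1 library.

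Over all regions, the F test called 40 genes, each of them also called in at least 1 of the 6 pairs of regions, and 759 genes had an unadjusted p under 0.05. MAB21L1 and LHX9 had the smallest adjusted p of 5.9e-04. MAB21L1 had 159 ± 71.6 in the root, 342 ± 85.6 in the ascending aorta, 243 ± 28.1 in the arch and 14.1 ± 1.67 in the descending aorta. LHX9 had 50.1 ± 10.5 in the root, 0.540 ± 1.21 in the ascending aorta, no read in the arch and 9.54 ± 6.17 in the descending aorta. edgeR called 21 genes and DESeq2 174, and limma with the adipocyte covariate called 5 and with the block 156. Without the block, the count was 23 without root 1, 19 without root 2, 25 without root 4, 23 without root 5 and 22 without descending 1.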

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

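The tests of explanations in this part, and the counts over other splits of the libraries, were chosen after the results had been seen.

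The pattern weighed here is the set of 16 genes called lower in arch than in root, with a median log2 change of -3.64. Within the 5 root libraries these genes did not rise with the adipocyte marker score. Their median slope on it was -0.0878 (-0.141 to -0.0126 with 1 root library left out), over scores from 7.06 to 10.6. This cannot decide whether adipose tissue carried with the root is their source. A call favors genes with little spread within root, so genes that follow the score are less likely to be among the 16. The adipocyte markers, lower in the arch as a list, had no member called. The ascending libraries do not exclude adipose tissue either. Ascending 2 had a score of 9.22, and the others of its region 4.74 to 6.49. It alone among them had reads of LHX9 (2.70) and NKX2-5 (5.40), values close to the floor. Without ascending 2, the adipocyte and cardiac transcription factor calls in arch against ascending both ended. With the score as a covariate the median log2 change of the 16 genes went from -3.64 to -3.65. The median standard error went from 0.565 to 0.790. Single changes moved toward 0 for IRX2 (-3.60 to -2.54), TCF21 (-6.28 to -5.14) and NKX2-5 (-5.34 to -4.19). They did so too for GATA4 (-9.70 to -8.81), LHX9, HAND1, GATA5, STC2 and PKP2. Among the lower genes named for this comparison, only those of SALL3 (-6.59 to -6.68) and C8orf49 (-5.74 to -5.97) moved away from 0. How far wider errors and smaller changes each ended the calls was not tested. For heart muscle carried with the root, a panel of MYH6, MYH7, TNNT2, TNNI3, MYL7 and NPPA argues against it as the source. In 4 of the 5 root libraries the most abundant of the panel lay below the median gene of the pattern, root 3 being the exception (MYH7 at 5910 against 286). Other heart muscle transcripts were not compared. Mesothelial or epicardial cells may contribute, since 6 of their abundant transcripts had a median log2 change of -1.48 (KRT19 had 409 ± 164 in the root and 162 ± 50.1 in the arch), and a difference in regional identity, which was not tested, stays open too.

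Regrouping the libraries at random gave chance as an explanation of the counts little room in 4 comparisons. For arch against root only the real split, 1 of 56, gave as many as 24 calls, the highest other giving 1. For ascending against root 1 of 100 splits drawn gave as many as 17, the highest other giving 4. For distal against proximal 1 of 100 gave as many as 18, the highest other giving 8, and over any region 2 of 100 gave as many as 40, the highest other giving 44. These splits treat libraries as independent, which the correlation within runs of sample codes argues against. Splits that moved region labels only within those runs were therefore counted too, and for each of the 4 counts 1 of 100, the real one, gave as many. The highest other gave 1, 1, 3 and 3 in the order above, so the share of these splits with as many calls was under 0.05. This makes chance unlikely for these 4 counts but does not exclude it, since the runs are not a stated design. For arch against ascending limma called 0 genes (358 at an unadjusted p under 0.05, 0 by edgeR and 3 by DESeq2). All 56 splits give at least 0 by necessity, so this count says nothing about chance. One of those other splits called 891 genes, which points to a structure of the samples beyond their region. It parted none of the 3 pairs of libraries that share a run, but 5 further splits that parted none gave at most 3 calls, so the runs alone do not explain it. Its smaller group held the 3 lowest quality weights of the 8 libraries, and its cause stays open.

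Single libraries that stood far from the other 4 of their region were found in 20 of 160 groups of values tested (12.5%), 10 in root and 10 in ascending. The values were those of named genes and of library depth and composition, all in the same libraries. Chance gives about 1 in 20 for independent, normally distributed values. These values are not independent, so a comparison of 12.5% with that rate decides nothing. In 3 of the 20 the other 4 libraries had no read, and any single nonzero value is then certain to stand apart, so these 3 carry no weight in that comparison. In root 1, C7, a complement gene, had 20172, below 25346 to 27586 in the others. In root 2, RERG had 1865, below 3230 to 3895, and DLX2 had 4.82 where the others had no read. In root 3, ST8SIA6 had 154, above 53.1 to 70.7, and the most abundant gene took 1.77% of the reads (95% Wilson interval 1.77% to 1.78%), below 2.23% to 2.29%. In root 4, HOXA4 had 0, below 9.49 to 23.6, CLEC18B had 65.7, above 33.4 to 40.5, and LRRC15 had 74.8, above 14.7 to 23.3. In root 5, FOXD1 had 46.8, above 15.7 to 21.5, and TBX20 had 736, below 1390 to 1583. In ascending 1, RERG had 2397, below 3077 to 3300. Its most abundant gene took 4.72% of the reads (95% Wilson interval 4.71% to 4.72%), above 2.40% to 2.60%, and its 10 most abundant took 18.8% (18.8% to 18.8%), above 12.4% to 14.1%. In ascending 2, LHX9 had 2.70 and NKX2-5 had 5.40 where the others had no read, and ASTN2 had 862, above 445 to 534. In ascending 3, DES had 1417, below 8018 to 15146. In ascending 4, HSPB3 had 40.2, above 8.10 to 12.2, and LRRC15 had 0, below 3.05 to 4.61. In ascending 5, KIAA1107 had 281, above 0 to 1.49.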

How the results depend on the processing

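The adipocyte covariate was chosen after the results had been seen, and the other alternatives before the data were examined. Counts of called genes stayed within 1.5 times their value with a pseudocount of 0.25, quantile normalization, equal medians and robust moderation. They were 24, 17, 0, 4, 33, 7 and 18 for arch against root, ascending against root, arch against ascending, descending against arch, descending against root, descending against ascending and distal against proximal, and 40 over any region. The cause of the changes below was not tested unless stated.

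With a pseudocount of 4 the counts rose to 7 for descending against arch, 50 for descending against root and 11 for descending against ascending. Without a filter they were 20, 54 and 24 for these comparisons, 32 for distal against proximal and 61 over any region. With library quality weights arch against root gave 41. With the compared regions alone in the fit, and so fewer samples, limma called 0 for descending against arch and 2 for descending against ascending. edgeR called 9 for arch against root, 14 for descending against root, 3 for descending against ascending, 8 for distal against proximal and 21 over any region. It called 12, 0 and 4 for ascending against root, arch against ascending and descending against arch. DESeq2 called 101, 80, 3, 19, 122, 31, 70 and 174 in the order above. On simulated counts 45 of its 200 calls for arch against root were unchanged genes, but those libraries were simulated as independent, unlike the real ones. The 9 edgeR calls for arch against root were all among the 24 of limma, and DESeq2 called 23 of the 24. With the adipocyte covariate limma called 0 for arch against root, 2 for ascending against root, 3 for descending against root, 0 for distal against proximal and 5 over any region. At an unadjusted p under 0.05 it had 848 genes for arch against root and 1631 for distal against proximal.

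Leaving out 1 library gave 12 to 35 calls for arch against root (13 without root 1, 12 without root 2, 15 without root 4, 13 without root 5, 14 without arch 1 and 13 without arch 3). For ascending against root it gave 8 to 18 (8 without root 1, root 2 or root 5), and for arch against ascending 0 to 1 (1 without ascending 5 or arch 2). It gave 4 to 16 for descending against arch (16 without descending 2), 2 to 42 for descending against root (2 without descending 1) and 4 to 27 for descending against ascending (4 without descending 1, 27 without descending 2). It gave 2 to 30 for distal against proximal (2 without descending 1, 30 without descending 2). Over any region it gave 19 to 52 (23 without root 1, 19 without root 2, 25 without root 4, 23 without root 5 and 22 without descending 1). A descending library left alone was assumed to vary like the other regions. Of 56 calls of named genes, 22 held whichever library was left out, and 3 under every other alternative.

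Some lists and 1 gene changed direction when a single library was left out. Unadjusted p-values over all omissions ranged from 2.8e-06 to 0.954 for endothelial markers in ascending against root (0.954 without ascending 3). They ranged from 1.7e-05 to 0.860 for the same list in arch against ascending (0.748 without ascending 3), and from 9.1e-06 to 0.417 for T and NK cell markers there (0.417 without ascending 5). The range was 1.1e-06 to 0.938 for neutrophil markers in arch against root (0.938 without arch 2), where the log2 change of CSF3R ranged from -0.0131 without arch 2 to 1.49. For descending against arch it was 1.1e-06 to 0.891 for inflammatory genes (0.891 without descending 1) and 1.6e-13 to 0.154 for proliferation genes (0.0704 without descending 2). Without descending 2 contractile smooth muscle genes reversed in descending against root (0.219, range 1.7e-14 to 0.219) and in distal against proximal (0.758, range 2.6e-11 to 0.758). Of 84 list calls, 20 held with an estimated correlation and 64 did not.

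Sample codes in the labels were cut into 6 runs, 4 of them with more than 1 library. A run holds consecutive numbers that go downstream along the aorta, and a new run starts where the next number is missing or its region is not further downstream. This is a hint from the data and not a stated design. Each of the 13 libraries in those runs deviated from its region's mean most like a library of its own run, among libraries of other regions. The mean correlation of deviations was 0.394 within runs and -0.0968 between runs (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). With the run as a block limma called 107, 125, 0, 17, 147, 21, 55 and 156, in the order above, with 810 genes at an unadjusted p under 0.05 for arch against ascending. The 24 and 17 genes called for arch and ascending against root were all among them. Of the named genes, 34 results gained a call with the block and none lost one, while 8 of the 84 list calls were lost. At this depth a count of 0 allows up to 3 reads per library, a value of 2.03 to 4.17.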

Other observations

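The genes described in this part were chosen after the values had been seen. Several signalling and matrix genes called over any region were highest in the root and lowest in the descending aorta, most of them outside the rule for named genes. RSPO1, an enhancer of Wnt signalling, had 302 ± 140 in the root, 70.6 ± 34.9 in the ascending aorta, 40.3 ± 22.7 in the arch and 12.9 ± 7.29 in the descending aorta (SD, n = 5, 5, 3 and 2; limma adjusted p over any region 0.0143). NRG1, encoding neuregulin, had 331 ± 98.0, 64.7 ± 38.5, 46.9 ± 38.2 and 24.6 ± 0.622 in the same order (limma adjusted p = 0.0423). GDF6, a BMP-family ligand gene, had 345 ± 78.3, 144 ± 21.3, 144 ± 74.8 and 68.2 ± 31.6 (limma adjusted p = 0.0356). COMP had 15741 ± 3467, 6712 ± 3380, 3717 ± 2150 and 1294 ± 465 (limma adjusted p = 0.0126).

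Of the 23 HOX genes shown, 21 had their highest mean in the descending aorta, all but HOXA2 and HOXA3, and 3 of the 21 (HOXA4, HOXA6 and HOXB7) were called over any region. Others did not pass. HOXC6 had a mean of 119 in the descending aorta against 4.31, 9.47 and 6.11 in root, ascending aorta and arch (limma adjusted p over any region 1). HOXD3 had 119 against 21.998, 19.8 and 18.5 (limma adjusted p = 0.688), and HOXA5 had 257 against 5.48, 17.5 and 9.86 (limma adjusted p = 0.319). The gene model of HOXA3 spans HOXA5, so reads of HOXA3 can be part of the HOXA5 value.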
